A study of Mus musculus with 4 samples.

How the data were processed

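Droplet single-cell RNA sequencing of kidney was analysed in 4 libraries from male C57BL/6 mice after ischemia-reperfusion (I/R) injury. The groups were day 5, day 14 and day 28 without L. casei Zhang (Lac.z), and day 5 after 4 weeks of daily gavage with 1e9 colony-forming units of this bacterium. Each group had 1 library, and how many animals a library held is not given in the sources used here. What the mice without Lac.z received by gavage is not given in the sources used here. An uninjured kidney was not analysed here.

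The deposited matrices held counts: whole numbers of unique molecular identifiers (UMIs) per gene and barcode, not normalised, per the file headers and the values themselves. The tissue had been digested with enzymes, strained and treated with red blood cell lysis buffer, per the labels' protocols. The genome build was mm10, per the submitters' processing notes. The matrix headers named software version 3.0.2 for both day 5 libraries and 3.1.0 for days 14 and 28, so the version cannot be told apart from the time after injury. The aligner and the gene annotation are not given in the sources used here. Each matrix listed 31053 genes, and gene names and identifiers were taken from the files. The lowest barcode totals were 502 to 509 UMIs, so barcodes below about this size had been left out before deposit.

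Barcodes with at least 200 genes and at most 50% mitochondrial UMIs were kept. The filters left 7086 barcodes in the day 5 library, 7043 in the day 5 Lac.z library, 9572 at day 14 and 14138 at day 28. Doublet scores were computed per library with Scrublet as implemented in scanpy, and the barcodes with the highest scores were removed at a rate of 0.8% per 1000 barcodes. This removed 478, 460, 858 and 1762 barcodes in the same order, which was 6.75%, 6.53%, 8.96% and 12.46%. Scrublet's own threshold would have marked 186, 66, 79 and 194 barcodes. The kept cells numbered 6608, 6583, 8714 and 12376.

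Cells of all 4 libraries were clustered together, without batch correction. UMIs were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and Leiden clustering ran on 20 neighbours at resolution 1 with seed 1. A cluster was called "X-like" from cell type markers fixed before the data were examined. It needed a median marker score of at least 1 on the log2 scale, a lead of at least 0.75 over the next class and at least 3 detected markers. It also needed no more markers of another class than of its own among its 10 leading genes, and erythroid cells needed 20% haemoglobin UMIs. These naming thresholds were set after the clusters had been seen, because haemoglobin RNA, often in a few barcodes, first gave non-erythroid clusters that name. They kept 4 clusters out of every class. Cluster 15, with tubule and injury genes (Havcr1, Spp1, Vcam1), held 1.98% of cells at day 5, 2.05% at day 5 with Lac.z, 4.10% at day 14 and 0.921% at day 28. Cluster 17, with a median of 1169 UMIs and led by Ccdc152, haemoglobin and macrophage genes, held 7.17%, 0.395%, 0.241% and 0.121%. At day 5, 9202 of its 9215 haemoglobin UMIs lay in 2 cells. The cluster had 14 macrophage markers detected but stayed unnamed because its leading genes held more haemoglobin genes than macrophage markers. Cluster 18 (Ccl17, Cd209a, Ccr7) held 3.03%, 1.31%, 1.62% and 0.493%, and cluster 24 (immunoglobulin genes) held 0.787%, 0.410%, 0.792% and 0.396%.

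Shares of cells per class carry exact Clopper-Pearson 95% intervals, and ratios of shares carry exact conditional intervals. For expression, UMIs were summed per library and class and scaled to UMIs per 1000000 of that sum (CPM), in classes with at least 50 cells in both libraries. A gene was measured with at least 50 UMIs over both libraries. Ratios of CPM carry exact conditional binomial 95% intervals, and sums of UMIs exact Poisson intervals. All these intervals cover counting error only. With 1 library per group there was no replicate spread, no test was run and no p-value is given. A gene, a list median or a share was called higher or lower at a ratio of at least 1.5, a rule of size fixed before the data were examined. Counts of genes past this rule use the log2 ratio with 1 UMI added to each sum. No direction is read from list medians within 1.5-fold. Genes with near-identical copies, such as Ifit3b and Ifit3, Serpina1a and Serpina1f, Cyp4a14 and Cyp4a10, H2-Q6, Hist1h2ap, Ftl1-ps1 and Hspa1b, are uncertain because their reads can be split between copies.

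Gene lists for injury, transport, metabolism, inflammation, repair, matrix, proliferation, lymphocyte and endothelial state and RNA quality were fixed before the data were examined. A list with at least 5 measured members (3 for markers and haemoglobin) was summarised by the median log2 ratio of its members. The interval of the median came from 1000 Poisson draws of the counts. The median was placed among 10000 random lists matched on expression in 20 bins, as a description of these libraries. The genes named per class were the 3 with the highest and the 3 with the lowest ratio (1 UMI added to each sum) in the macrophage-like, proximal tubule-like and T cell-like classes. They needed at least 100 UMIs, at least 50 CPM in the higher library and at least 25% of the highest CPM of any class in that library. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor and predicted genes, Y-linked genes and Xist were not named by this rule. Up to 2 members with the highest and 2 with the lowest ratio were taken per list. Some items that were measured are not reported here. Other genes named in the text were chosen after their values were seen: Isg15, H2-Aa, Cd74, Mki67, Top2a, Havcr1 (where it is not among the extremes), Acta2 and the clock genes. The 8 results followed through every alternative were chosen after the list medians had been seen but before the values of any alternative were seen. They were the macrophage-like share in the 3 comparisons, the interferon list in macrophage-like cells with Lac.z, the class II list in macrophage-like cells at days 14 and 28, and the injury list in proximal tubule-like cells with Lac.z and at day 28.

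For shares of cells with a UMI, each cell was also thinned to 2000 UMIs, and shallower cells were left out. The alternatives covered mitochondrial limits of 25% or none, at least 500 genes per cell, no doublet removal, resolutions 0.5 and 2, libraries clustered separately and the mean of each cell's own CPM. They also covered scaling by the median ratio, totals without mitochondrial genes, minimums of 20 or 200 UMIs per gene, and members at 25% or more of the highest class. A further 4 alternatives were chosen after seeing the data: cluster 17 counted as macrophage-like, cluster 15 counted as proximal tubule-like, cells under 1000 UMIs or with at least 1% haemoglobin left out, and a single cluster per class (cluster 2 for macrophage-like, cluster 1 for proximal tubule-like cells).

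The calculations were tested on simulated data. Counts were drawn from the mean gene profile of each pair of libraries at 2% of each library's total, with known changes. The neutrophil-like (463166 UMIs at day 5), endothelial-like (905645) and fibroblast or mural-like classes (943441) held fewer UMIs than this. The rule of 1.5 recovered 95.7% of genes changed 2-fold for Lac.z at day 5 (6438 genes), 93.5% for day 14 (6827 genes) and 94.5% for day 28 (7090 genes), and 100.0% of those changed 3-fold or 4-fold in each comparison. Unchanged genes passed the rule in 3.61% to 4.56% of cases. The draws held Poisson error only, with no spread between animals, preparations or cell states. These rates are therefore not error rates for the comparisons of the real libraries. In simulated cells of 6 classes, at least 94.7% received their class's name, and 150 cells with a programme outside the markers and 150 with none stayed unnamed. Each simulated class was made by raising the same markers that the naming rule reads and damping the other markers, at 5000 UMIs per cell. A high share was therefore built in, and mixed clusters of real cells were not tried. The tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, python-igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.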

Results

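Kidneys of male C57BL/6 mice were profiled by single-cell RNA sequencing after I/R, in which the blood supply of the kidney is blocked and then restored. The 4 libraries comprised I/R kidney at days 5, 14 and 28 and I/R kidney at day 5 after oral Lac.z, a probiotic Lactobacillus strain, with 1 library per group. The day 5 library held 82727595 UMIs in 8424 barcodes, and the day 5 Lac.z library 76678882 UMIs in 8168 barcodes. The day 14 library held 89408767 UMIs in 11203 barcodes, and the day 28 library 104454319 UMIs in 15583 barcodes. The median barcode had 8102, 7874, 5590 and 4864 UMIs in this order. Its mitochondrial share was 5.25% at day 5 against 14.3% with Lac.z, 15.9% at day 14 and 18.6% at day 28. Within classes of kept cells the day 5 library was not the lowest. The medians were 21.4%, 18.0%, 17.6% and 19.6% in proximal tubule-like cells, in the same order. In macrophage-like cells they were 3.78%, 2.99%, 2.85% and 2.93%. After filtering, 6608, 6583, 8714 and 12376 cells were kept. All libraries carried the male pattern stated for the mice, with 4271 to 6605 UMIs of the Y-linked gene Ddx3y and 4 to 11 UMIs of Xist. Because each group had a single library, no difference below has a replicate check, and a difference between groups cannot be separated from a difference between the animals or preparations. What the mice without Lac.z received by gavage is not given in the sources used here, so an effect of the gavage is not separated from that of Lac.z. The 3 comparisons share the day 5 library without Lac.z, so any feature of that library enters all of them.

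The first comparison asked whether Lac.z given before injury went with a different cell makeup at day 5. Macrophage-like cells made up 49.0% (95% interval 47.8 to 50.3) of the day 5 library and 23.1% (22.1 to 24.2) of the Lac.z library, which was 2.12-fold lower (2.00 to 2.26). Proximal tubule-like cells made up 20.9% without and 59.8% with Lac.z, a share 2.86-fold higher (2.69 to 3.04). The shares of T cell-like (6.81% and 4.31%), endothelial-like (2.82% and 1.73%) and fibroblast or mural-like cells (0.817% and 0.304%) were 1.58-fold, 1.63-fold and 2.69-fold lower with Lac.z. Distal convoluted tubule-like and collecting duct intercalated-like cells each had shares 2.01-fold higher. Neutrophil-like (2.71% and 1.98%), monocyte-like (0.560% and 0.699%) and loop of Henle-like cells (0.742% and 0.911%) differed by less than 1.5-fold. Among named immune cells the macrophage-like share was 81.2% without and 75.2% with Lac.z, and the monocyte-like share (0.928% and 2.27%) was 2.45-fold higher (1.55 to 3.88). Shares sum to 100, so a higher yield of tubule cells alone lowers every other share. With a mitochondrial limit of 25%, the ratios of T cell-like (0.708), endothelial-like (0.720) and intercalated-like (1.37) shares no longer reached 1.5-fold, and the distal convoluted tubule-like ratio turned to 0.718 when libraries were clustered separately.

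**Figure D1:**
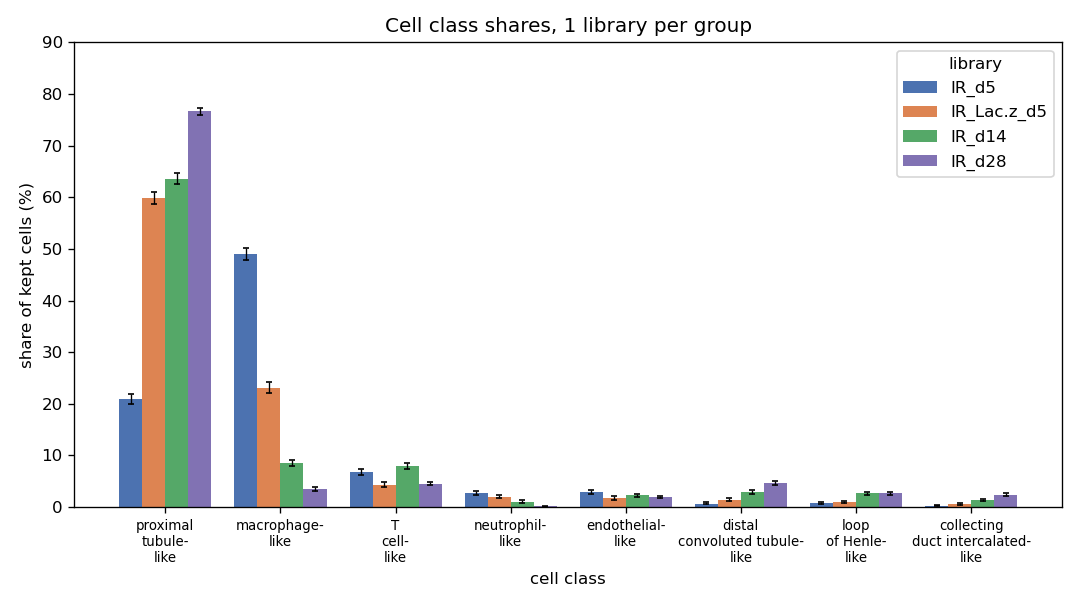
Share of kept cells (percent, y axis) in 8 cell classes (x axis), with a bar for each of the 4 libraries and exact binomial 95% intervals that cover counting error only. Macrophage-like cells ranged from 49.0% at day 5 to 3.47% at day 28, and proximal tubule-like cells from 20.9% to 76.6%.

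Interferon-stimulated genes were higher with Lac.z in macrophage-like cells at day 5. Of 28 measured members of the interferon response list, 27 were higher and none lower by 1.5-fold, with a median ratio of 4.37 (log2 2.13, 2.09 to 2.18), above all 10000 matched random lists. Irf7 (ENSMUSG00000025498), a transcription factor that amplifies type I interferon responses, was 14.0-fold higher (13.3 to 14.8; 38.1 and 534 CPM). Isg15 was 8.23-fold higher and Ifi44 had a log2 ratio of 4.31, whereas Gbp2 was 1.55-fold higher and Gbp5 had a ratio of 1.20. At least 1 Irf7 UMI was seen in 23.6% of macrophage-like cells without and 82.4% with Lac.z, or 6.78% and 57.8% after thinning to 2000 UMIs, which left out 27 and 14 cells. In distal convoluted tubule-like cells, which served as background, the shares were 2.22% and 4.44%, at median depths of 5448 and 5774 UMIs against 12170 and 11179 in macrophage-like cells. The named genes with the highest ratios were Ifit3b (ENSMUSG00000062488; 18.2-fold, 15.4 to 21.5), Spon1 (ENSMUSG00000038156; 17.9-fold), which encodes the matrix protein F-spondin, and Plac8 (ENSMUSG00000029322; 16.3-fold). Those with the lowest were F13a1 (ENSMUSG00000039109; 2.77-fold lower, 2.63 to 2.91), which encodes a subunit of coagulation factor XIII, Ifi27 (2.19-fold lower) and Igfbp4 (2.13-fold lower).

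Other macrophage programmes differed less between the day 5 libraries. Of 25 measured genes of the reparative and lipid-handling list, 6 were lower with Lac.z and 1 higher (median log2 -0.23). Fn1, which encodes fibronectin, was 2.36-fold and the haemoglobin scavenger receptor gene Cd163 2.28-fold lower, and Fabp4 had a log2 ratio of 0.59. In the inflammatory list, 3 of 29 members were higher and 2 lower (median log2 -0.09). The chemokine genes Cxcl10 and Ccl5 were 2.67-fold and 2.56-fold higher, and Il6 (161 and 15 UMIs) and Cxcl1 were 4.66-fold and 2.20-fold lower. The class II antigen presentation list had 1 of 13 members higher (Cd40, log2 0.68; median log2 0.09), and none of 16 glycolysis genes reached 1.5-fold (median log2 -0.12). In the proliferation list, 1 of 22 members was higher (Mcm6, 1.51-fold; median log2 0.35), and in the matrix list 6 of 21 were higher and 2 lower (median log2 0.30), with Timp3 3.81-fold and Dcn (38 and 40 UMIs) 2.42-fold higher. The immediate early list had a median log2 of 0.04 and the mitochondrially encoded list of -0.15. Markers of proximal tubule were higher in the macrophage-like cells of the Lac.z library for 13 of 13 genes (median 4.05-fold), while macrophage markers had a median log2 of 0.06. The cytotoxic and regulatory lymphocyte list was higher in these cells for 3 of 5 measured genes (1.92-fold). Haemoglobin genes were lower (median log2 -3.36), but 13962 of 14264 haemoglobin UMIs at day 5 lay in 4 cells. Different clusters held the class in each library: cluster 11 held 58.8% of it with Lac.z, while clusters 2 and 9 held 50.1% and 41.3% of it without. Within cluster 2 alone the interferon median was log2 0.69, with 16 of 28 members higher and 1 lower. Plac8 was then higher by log2 0.72 (2.85 in all clusters without doublet removal), Ifit3b by 1.38 and Spon1 by 1.92, and Ifi27 no longer reached 1.5-fold (log2 -0.52).

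In proximal tubule-like cells, Lac.z went with higher interferon-stimulated genes and with higher Cyp4a14 and Cyp4a10 at day 5. All 23 measured interferon genes were higher, with a median ratio of 5.52, Rsad2 (8 and 629 UMIs) at 26.2-fold and Xaf1 at 17.9-fold. The level was low, with 1.33 list UMIs per cell without and 5.70 with Lac.z. In the Lac.z library, distal convoluted tubule-like cells held 3.91, loop of Henle-like cells 10.2 and macrophage-like cells 131 per cell. Whether free RNA from other cells gave the rise in proximal tubule-like cells was not tested. Cyp4a14 (ENSMUSG00000028715), which encodes a fatty acid omega-hydroxylase, was 4.85-fold higher (4.45 to 5.29; 49.2 and 238 CPM). Ifi27 was 3.06-fold higher. The named genes with the lowest ratios were Acsm3 (2.24-fold lower), AY036118 (1.96-fold lower) and Idi1 (1.89-fold lower), an enzyme gene of sterol synthesis. Idi1 no longer reached 1.5-fold within cluster 1 alone (log2 -0.58), where Cyp4a14 had a log2 ratio of 2.91. Of 24 fatty acid oxidation genes, 4 were higher and none lower (median log2 0.10), with Cyp4a10 at 2.15-fold and Cyp4b1 at a ratio of 0.815. In the short-chain fatty acid list, 2 of 17 genes were higher, among them Slc5a8 (1.56-fold), and 1 was lower (median log2 -0.10).

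The direction of tubular injury genes with Lac.z depended on which cells were counted as proximal tubule-like. In the class as named, of 23 measured members, 6 were higher and 2 lower (median log2 0.30, 0.27 to 0.41). The complement gene C3 was 2.93-fold, the fibrinogen chain gene Fgb 2.87-fold and Havcr1 (ENSMUSG00000040405), which encodes the injury marker KIM-1, 1.65-fold higher, while Ccl2 was 2.19-fold and Vim 1.91-fold lower. The median of this list depended on how cells were assigned: it was -0.24 at resolution 2 (3 of 27 members higher and 13 lower), -0.03 without a mitochondrial limit (3 of 23 higher and 3 lower) and 1.68 when libraries were clustered separately (25 of 28 higher and none lower). The class left out cluster 15, led by Havcr1, with 131 cells without and 135 with Lac.z. With these cells counted in the class, 3 of 28 injury genes were higher and 18 lower (median log2 -0.89), while the class itself had a 2.70-fold higher share. At resolution 2 the class held both clusters with Havcr1 among their leading genes (75 and 88 cells without, 199 and 282 with Lac.z). With separate clustering such a cluster was outside the class without Lac.z (106 cells) and inside it with Lac.z (210 cells). Among proximal tubule transport genes, 1 of 20 was higher (Aqp1, 1.61-fold; median log2 0.17). No member of the oxidative phosphorylation (20 genes, median log2 -0.17), nicotinamide metabolism (19 genes, 0.03), oxidative stress defence (19 genes, -0.07) or cell death lists (14 genes, 0.04) reached 1.5-fold, with extremes of 0.735 for Cycs, 1.40 for Kynu, 0.747 for Prdx1 and 1.44 for Pmaip1. In the glycolysis list, Pfkfb3 was 2.25-fold higher and Pkm 2.10-fold lower among 13 genes (median log2 -0.16). The immediate early list had 10 of 21 members higher and 1 lower (median log2 0.58; -0.14 within cluster 1). The mitochondrially encoded list had a median log2 of -0.13, markers of macrophage were lower for 10 of 13 genes, those of fibroblast or mural cells were higher for 4 of 5 (median 9.65-fold), and haemoglobin genes were higher (median log2 7.25), with 28685 of 30052 UMIs in 4 cells of the Lac.z library. Cluster 4 held 26.1% of the class without and 40.4% with Lac.z.

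T cell-like and endothelial-like cells also had higher interferon-stimulated genes in the Lac.z library. In T cell-like cells 18 of 26 members were higher and none lower (median ratio 2.27; log2 1.77 over the 15 members with at least 200 UMIs), with Ifit1 at 6.72-fold and Ifi27l2a at 6.24-fold, and in endothelial-like cells 24 of 26 were higher and none lower (median ratio 2.67), with Ifit2 at 8.22-fold. Gzmb, which encodes the cytotoxic protease granzyme B, was 3.06-fold and Il2ra 2.08-fold higher in T cell-like cells, where 3 of 18 genes of the cytotoxic and regulatory list were higher and none lower (median log2 0.23). Natural killer cell markers in this class had 1 of 9 members higher and none lower (median log2 0.39). No natural killer cell-like cluster was named, so a different share of natural killer cells within the class was not separated. Ifit3b (12 and 101 UMIs) was 12.7-fold higher (log2 2.77 without doublet removal). Cenpf (1.88-fold), Cd40lg (1.76-fold) and Yipf3 (1.74-fold) were lower, and Cenpf no longer reached 1.5-fold at resolution 2 (log2 -0.42). Jchain and Mzb1, genes of antibody-secreting cells, were also named by the rule, but 978 of 980 Jchain UMIs and 196 of 198 Mzb1 UMIs lay in 3 cells. With separate clustering Mzb1 turned to log2 -1.76 and Jchain had 0.66. In the endothelial list, 4 of 14 members were higher and 1 lower (median log2 0.22), with the leukocyte adhesion gene Vcam1 at 2.57-fold, Cxcl12 at 1.63-fold and Aplnr 2.26-fold lower. Proliferation genes in T cell-like cells had 3 of 22 members lower (median log2 -0.19). Markers of other classes also differed: those of proximal tubule were higher for 4 of 4 genes in T cell-like cells (median 5.31-fold) and 5 of 5 in endothelial-like cells (2.22-fold), and macrophage markers were lower for 4 and 5 of 6 (log2 -2.03 and -1.78). Class II genes were lower for 5 of 7 in T cell-like and 5 of 6 in endothelial-like cells. The mitochondrially encoded list had medians of log2 -0.02 and 0.22 in these classes.

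**Figure D2:**
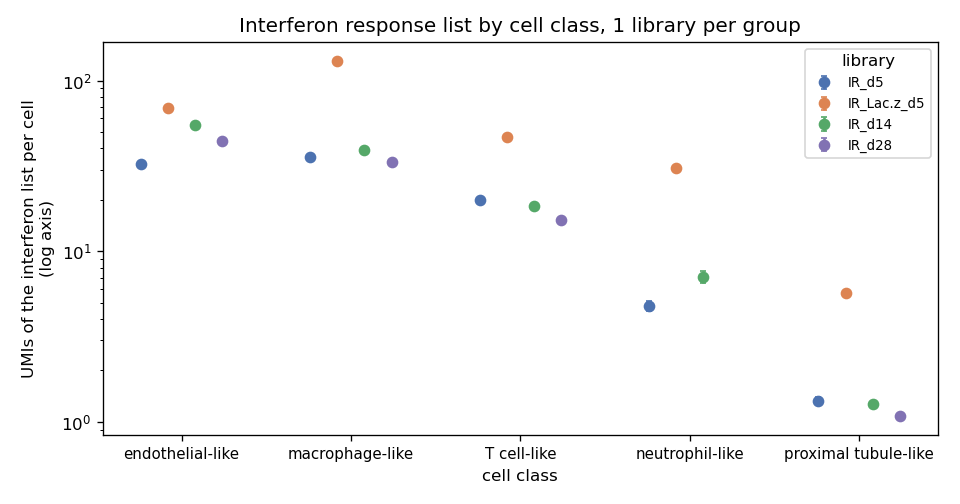
UMIs of the interferon response list per cell (y axis, log axis) in 5 cell classes (x axis), with a point for each library of at least 50 cells in the class and exact Poisson 95% intervals. Macrophage-like cells held 131 UMIs per cell in the Lac.z library and 33.5 to 39.4 in the other 3 libraries, and endothelial-like cells held 68.7 with and 32.2 without Lac.z at day 5.

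The second comparison followed the kidney from day 5 to days 14 and 28 without Lac.z. Macrophage-like cells made up 8.58% of cells at day 14 and 3.47% (3.15 to 3.80) at day 28, which was 5.71-fold (5.28 to 6.20) and 14.1-fold (12.8 to 15.7) lower than the 49.0% at day 5. Neutrophil-like cells were 2.57-fold lower at day 14 (1.06%) and 18.6-fold lower at day 28 (0.145%, 18 cells). The share of T cell-like cells was 7.99% at day 14 and 4.54% at day 28, against 6.81% at day 5. Within named immune cells, T cell-like cells made up 11.3%, 42.0% and 51.7% at days 5, 14 and 28, and macrophage-like cells 81.2%, 45.1% and 39.5%. The monocyte-like share of immune cells was 4.03-fold and 2.68-fold higher at days 14 and 28, while over all cells its ratio was 1.27 at day 14 and it was 2.57-fold lower at day 28. Proximal tubule-like cells made up 63.6% at day 14 and 76.6% at day 28. Shares of distal convoluted tubule-like, loop of Henle-like and intercalated-like cells were 4.31-fold, 3.54-fold and 4.63-fold higher at day 14 and 6.86-fold, 3.55-fold and 8.43-fold higher at day 28. With separate clustering the distal convoluted tubule-like ratios were 1.51 and 2.38. Time after injury could not be separated from the software version named in the matrix headers.

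Macrophage-like cells at days 14 and 28 had more class II antigen presentation RNA and less of the genes of lipid-handling macrophages than at day 5. Of 13 class II genes, 10 were higher and none lower at each day, with median ratios of 2.28 at day 14 (log2 1.19, 0.99 to 1.23) and 2.74 at day 28 (log2 1.45, 1.39 to 1.52). H2-Ab1 (ENSMUSG00000073421) was 3.70-fold higher at day 14 (2741 and 10126 CPM) and 4.59-fold at day 28, Cd74, the invariant chain, 3.28-fold and 3.72-fold, and H2-Aa 3.64-fold at day 14. H2-Ob, with 76, 53 and 32 UMIs at days 5, 14 and 28, was 4.14-fold and 7.06-fold higher, and H2-Oa 5.99-fold higher at day 28. In the reparative and lipid-handling list, 16 of 25 genes were lower and none higher at day 14 (median 1.93-fold lower), and 19 of 26 were lower and 1 higher at day 28 (median 1.78-fold lower). Gpnmb (ENSMUSG00000029816), a glycoprotein gene of lipid-laden macrophages, was 19.4-fold lower at day 14 (15.6 to 24.5; 210 and 10.8 CPM). At day 28 no Gpnmb UMI was counted against 9220 at day 5, which was at least 183-fold lower against a floor of 3 counts in the library. A Gpnmb UMI was seen in 22.5% of macrophage-like cells at day 5, 2.41% at day 14 and 0 of 429 cells at day 28, which allows a share of cells with a Gpnmb UMI of up to 0.856% at this depth and sets no limit on cells that express it below detection. In T cell-like cells the shares were 1.56%, 0.575% and 0%, and after thinning those of macrophage-like cells were 11.4%, 1.34% and 0%. Median depths were 12170, 9227 and 5546 UMIs in macrophage-like and 4667, 4456 and 3233 UMIs in T cell-like cells. Arg1 (ENSMUSG00000019987), which encodes arginase 1, was 8.77-fold (7.74 to 9.97) and 23.7-fold (16.9 to 34.5) lower, and Syngr1 6.46-fold and 20.8-fold lower. Spp1, which encodes osteopontin, was 24.1-fold lower at day 28. Retnla was higher at day 28, with 8 UMIs at day 5 and 291 at day 28, of which 287 lay in 6 cells.

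The same cells differed from day 5 in inflammatory, interferon, proliferation and glycolysis genes. Il1b (ENSMUSG00000027398) was 5.33-fold (5.23 to 5.42) and Nlrp3, an inflammasome sensor gene, 4.88-fold higher at day 14, and at day 28 Il1b was 4.73-fold and Ccl5 12.8-fold higher. The inflammatory list had 8 of 29 members higher and 2 lower at day 14 (median log2 0.33; Ccl6 2.82-fold lower) and 11 higher and 7 lower at day 28 (median log2 0.25). Interferon genes were higher for 14 of 28 members at day 14 (median ratio 1.53) and 25 of 28 at day 28 (median ratio 2.16), with Irf7 at 2.72-fold and 5.24-fold, and none was lower. Proliferation genes were lower for 14 of 22 members at day 14 (median 2.61-fold) and 15 of 22 at day 28 (median 1.94-fold), with the mitotic gene Cenpf 9.50-fold lower at day 14. Glycolysis genes were lower for 8 and 9 of 16 members and higher for 1 (median log2 -0.59 and -0.76). In the matrix list 8 of 20 members were higher and 2 lower at day 14 (median log2 0.36), and 7 of 18 higher and 5 lower at day 28 (-0.28), with Timp3 7.14-fold and 10.5-fold higher and Fn1 7.02-fold lower at day 28. Other named genes were Fosb (5.35-fold) and Sik1 (4.94-fold) at day 14 and H2-Q6 (16.0-fold) and Dnase1l3 (11.7-fold) at day 28, all higher.

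Immediate early genes, which also respond to tissue dissociation, were higher in macrophage-like cells for 14 of 22 members at day 14 and 16 of 22 at day 28 (median log2 0.73 and 0.86), with 1 and 2 lower. Markers of proximal tubule were higher in these cells for 13 of 13 and 11 of 11 genes (median 9.21-fold and 16.5-fold), and monocyte markers had medians of log2 -0.61 and -1.76. The cytotoxic and regulatory lymphocyte list was higher for 2 of 5 genes at day 14 (log2 0.36) and 5 of 5 at day 28 (10.7-fold), and Ccl5 was the leading gene of the T cell-like cluster 7. The mitochondrially encoded list had medians of 0.09 and 0.24. Haemoglobin genes were lower (log2 -4.66 and -4.03), a direction set by the few haemoglobin-rich cells of day 5. Cluster 2 held 86.0% of the class at day 14 and 87.2% at day 28 but 50.1% at day 5, where cluster 9, in which Arg1 and Gpnmb were the leading genes, held 41.3%. Within cluster 2 alone, the class II medians were log2 0.57 at day 14, below 1.5-fold, and 0.90 at day 28. The same restriction took below 1.5-fold the day 14 medians of the reparative (-0.28) and interferon lists (0.39), Gpnmb at day 14 (-0.34), and proliferation (-0.20 and -0.18), glycolysis (-0.30 and -0.30) and immediate early genes (0.53 and 0.53) at both days. Syngr1 turned to 0.14 at day 14, Arg1 had -0.70 at day 14, and at day 28 the values were -2.94 for Gpnmb (1 UMI added), -1.08 for Syngr1 and -3.92 for Arg1, 3.06 for H2-Q6 and 2.18 for Dnase1l3. Gpnmb at day 28, which had log2 -9.10 with 1 UMI added, had -6.11 with at least 500 genes per cell and -6.53 without doublet removal. Glycolysis medians at days 14 and 28 also fell below 1.5-fold without doublet removal (-0.45 and -0.44) and with separate clustering (-0.29 and -0.47). They did so at day 28 with at least 500 genes per cell (-0.56), and at day 14 without a mitochondrial limit (-0.565), with scaling by the median ratio (-0.52) and with the mean of each cell's own CPM (-0.584). Without doublet removal, proliferation medians were -0.01 and -0.54 and the interferon median at day 14 was 0.52; it was 0.47 as the mean of each cell's own CPM and 0.56 for members at 25% or more of the highest class. Libraries clustered separately gave -0.58 for the reparative list, -3.10 for Gpnmb and -1.34 for Arg1 at day 14, 0.37 for the interferon list at day 14 and 2.47 for Retnla at day 28.

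**Figure D3:**
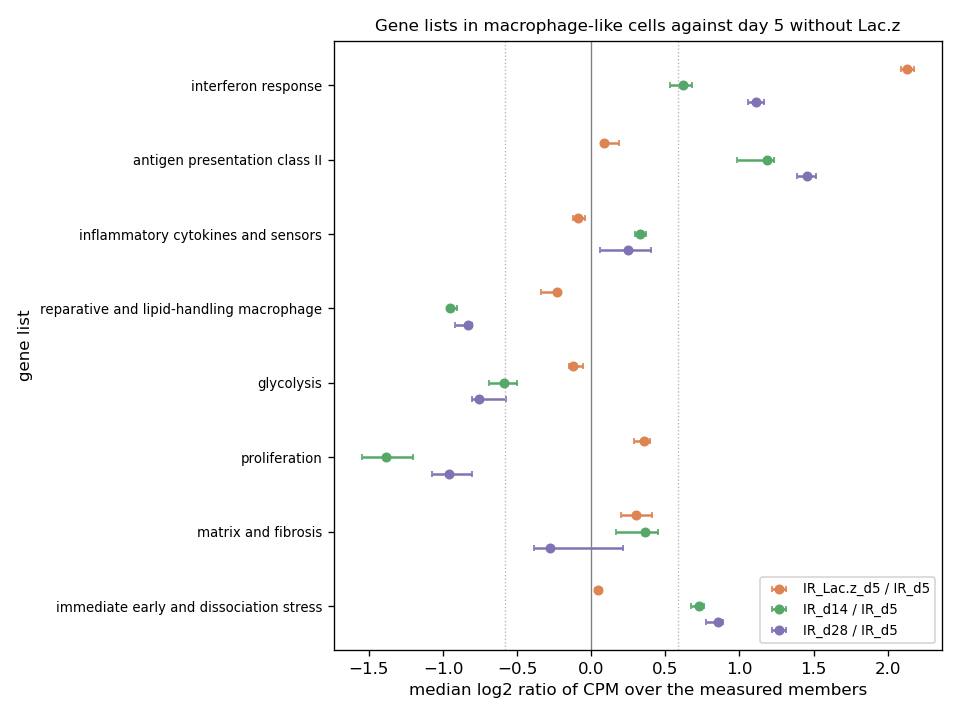
Median log2 ratio of CPM (x axis) of the measured members of 8 gene lists (y axis) in macrophage-like cells, for each of the other 3 libraries over day 5 without Lac.z. Bars are 95% intervals from Poisson draws, and dotted lines mark 1.5-fold. The interferon list stood at 2.13 with Lac.z, and the class II list at 1.19 and 1.45 at days 14 and 28.

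Proximal tubule-like cells at day 28 had lower tubular injury genes than at day 5, while at day 14 the direction depended on which cells were counted. At day 28, 16 of 24 members were lower and 2 higher, with a median 3.89-fold lower (log2 -1.96, -2.03 to -1.71), below all 10000 matched random lists. Havcr1 was 21.4-fold lower (13.9 and 0.647 CPM), the chemokine gene Ccl2 13.9-fold (51 and 19 UMIs), and the fibrinogen chain genes Fgg (ENSMUSG00000033860) and Fga 8.66-fold (8.03 to 9.33) and 3.75-fold lower. The stress and cell cycle arrest genes Cdkn1a (2.64-fold) and Gdf15 (2.55-fold) were higher. A Havcr1 UMI was seen in 4.19% of proximal tubule-like cells at day 5, 3.73% at day 14 and 0.274% at day 28, or 1.88%, 1.66% and 0.064% after thinning, which left out 104, 421 and 1681 cells. The share in T cell-like cells was 0.222%, 0% and 0.178%. These shares leave out cluster 15, led by Havcr1, which held 131, 357 and 114 cells at days 5, 14 and 28. With these cells counted in the class, the injury medians were log2 -1.34 at day 14 (2 of 28 genes higher and 23 lower) and -2.70 at day 28 (1 higher and 24 lower). Over all cells, the share of cluster 15 was 2.07-fold higher at day 14 (1.69 to 2.54) and 2.15-fold lower at day 28. The share of the class as named was 3.04-fold and 3.66-fold higher. The lower median at day 14 therefore does not mean a smaller share of cluster 15. This cluster scored 1.49 for proximal tubule and 1.47 for loop of Henle markers. Median depths in proximal tubule-like cells were 6900, 5912 and 4648 UMIs. At day 14, 7 of 24 injury genes were higher, among them Atf3 (log2 1.63) and Gdf15 (2.69-fold), and 8 were lower, among them Fgg (3.32-fold) and Ccl2 (3.28-fold), with a median log2 of 0.03. The day 14 median was -0.85 at resolution 2 and -0.72 within cluster 1. The day 28 median was -2.60 at resolution 2, -1.19 within cluster 1 and -0.59 over the 17 members with at least 200 UMIs.

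Genes of transport and of fatty acid metabolism were higher in part at both later days. The transport list had 5 of 20 members higher and 1 lower at day 14 (median log2 0.29) and 4 higher and 1 lower at day 28 (0.26). Slc16a1, which encodes the monocarboxylate transporter MCT1, was 2.29-fold and 3.09-fold higher at days 14 and 28, Aqp1 was 2.19-fold higher at day 14, and the sulphate transporter gene Slc13a1 was lower at both days (log2 -0.67 at day 14, 2.11-fold at day 28). Fatty acid oxidation genes were higher for 4 of 24 members at day 14 (median log2 0.35) and 5 of 24 at day 28 (0.22), and none was lower, with Cyp4a14 at 4.18-fold and 2.72-fold. The short-chain fatty acid list had 5 of 17 members higher at day 14 (median log2 0.12) and 5 of 18 at day 28 (0.21), and none lower, with Slc5a8 at 3.58-fold and 2.43-fold. In the nicotinamide list Ido2 was higher at both days (log2 1.53 at day 14, 2.71-fold at day 28) and Nmrk1 1.81-fold and 2.80-fold lower, with medians of 0.05 and 0.04 over 19 genes. Oxidative phosphorylation had no member past 1.5-fold at either day (0.04 and 0.07). Glycolysis had 3 of 14 members higher at day 14 (0.06) and 2 of 13 lower at day 28 (-0.14), oxidative stress defence 3 and 1 of 19 higher (0.02 and -0.06), and cell death 1 of 15 higher at day 14 (-0.05) and 4 of 15 lower at day 28 (-0.14; Tnfrsf1a 1.90-fold lower).

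Serpina1a (ENSMUSG00000066366; 31 and 5049 UMIs), an alpha-1-antitrypsin gene, was 41.5-fold higher (29.2 to 61.1) and Serpina1f 21.6-fold higher at day 14. Nr1d1 (ENSMUSG00000020889), which encodes the circadian repressor REV-ERB alpha, was 7.29-fold (6.43 to 8.30) and 5.34-fold (4.71 to 6.07) higher at days 14 and 28, and the circadian output gene Dbp 3.84-fold lower at day 28. Zbtb16 (9.64-fold) and Slc25a25 (5.22-fold) were higher at day 28, and Ftl1-ps1 (3.04-fold) and Spns3 (2.59-fold) lower at day 14. Proliferation genes were lower for 15 of 21 members at day 14 (median 3.08-fold), with Mki67 and Top2a 11.7-fold and 11.6-fold lower, and 5 were higher and 1 lower of 22 at day 28 (median log2 0.09). Immediate early genes were higher for 13 of 22 members at day 14 (median log2 0.72) and 6 of 22 at day 28 (0.40), with 1 and 2 lower. Interferon genes had 3 of 19 members higher and 9 lower at day 14 (median log2 -0.585), and 5 of 21 higher and 4 lower at day 28 (median log2 -0.13). The mitochondrially encoded list had medians of -0.27 and -0.14, haemoglobin genes of 1.78 and 2.83, and markers of macrophage were lower for 8 of 11 and 9 of 10 genes. Clusters 0 and 1 held 26.2% and 15.9% of the class at day 14 and 26.2% and 15.7% at day 28, while clusters 4 and 10 led at day 5 (26.1% and 19.4%). Some named genes led clusters nearly absent from a library: cluster 13 (Serpina1a, Serpina1f) held 6, 427 and 285 cells of the class at days 5, 14 and 28, cluster 6 (Nr1d1) 15, 754 and 1206, and cluster 23 (Mki67, Cenpf) 18, 8 and 141. With cluster 15 counted in the class, the immediate early median at day 14 was 0.43, and with a mitochondrial limit of 25% it was 0.585, just short of 1.5-fold. Within cluster 1 alone, the log2 ratios at day 14 were 1.44 for Serpina1a, 0.86 for Serpina1f, 0.87 for Nr1d1, 0.00 for the immediate early list and -0.12 for the proliferation list. At day 28 they were 0.40 for Nr1d1, 1.97 for Zbtb16, -3.26 for Dbp and -2.63 for Fga. The mean of each cell's own CPM gave 2.14 and 1.68 for Nr1d1 at days 14 and 28 and 0.36 for the immediate early list at day 14, and the proliferation median at day 14 was -0.29 over the 8 members with at least 200 UMIs.

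**Figure D4:**
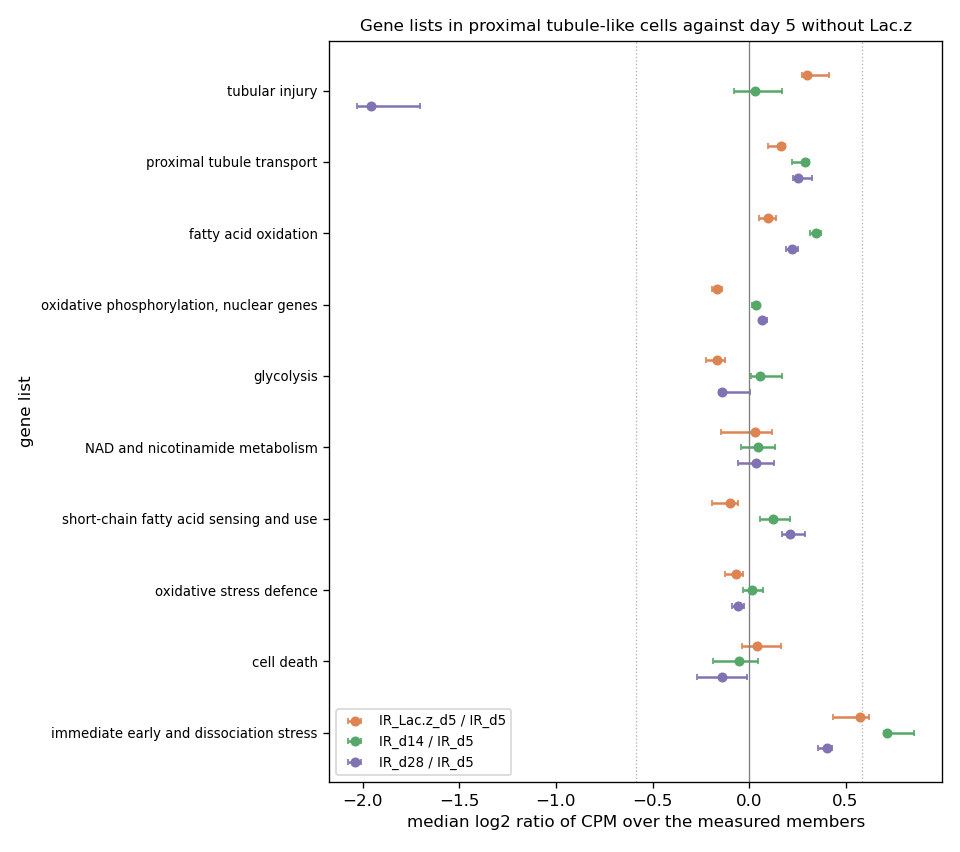
Median log2 ratio of CPM (x axis) of the measured members of 10 gene lists (y axis) in proximal tubule-like cells, for each of the other 3 libraries over day 5 without Lac.z. Bars are 95% intervals from Poisson draws, and dotted lines mark 1.5-fold. The tubular injury list stood at -1.96 at day 28 and at 0.30 and 0.03 in the Lac.z and day 14 libraries.

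T cell-like cells had lower proliferation genes at the later days, and some genes of the cytotoxic and regulatory list were higher. Proliferation genes were lower for 13 of 22 members at day 14 (median 1.71-fold) and 19 of 22 at day 28 (median 5.94-fold), and none was higher. Cenpf was 3.72-fold and 30.5-fold lower, Ube2c 3.57-fold lower at day 14, and Pclaf and Birc5 11.2-fold and 9.43-fold lower at day 28. At resolution 2 the proliferation medians were log2 0.02 and -0.30, and without doublet removal the day 28 median was -1.16 and Cenpf, Pclaf and Birc5 had -1.61, -1.35 and -1.45. Cenpf and Ube2c at day 14 had -0.63 and -0.84 at resolution 2. The integrin gene Itgae (ENSMUSG00000005947; 17 and 223 UMIs), a marker of tissue-resident T cells, was 9.09-fold higher (5.55 to 15.9) at day 14 (log2 2.40 from the mean of each cell's own CPM), and Cd7 4.86-fold at day 28 (log2 0.90 with separate clustering). Of the cytotoxic and regulatory list, 9 of 20 members were higher at day 14 (median log2 0.54; Pdcd1 2.91-fold, Gzmb 2.61-fold) and 6 of 19 at day 28 (0.24; Ikzf2 3.37-fold, Foxp3 2.90-fold), with none lower. Nr4a3 was 5.17-fold and 6.01-fold higher, Hist1h2ap 5.42-fold at day 14 (log2 4.75 at resolution 2) and the heat shock gene Hspa1b 10.6-fold at day 28 (log2 2.13 without doublet removal), and Arl6ip5 3.03-fold lower at day 14. Immediate early genes were higher in this class too (median log2 0.73 and 1.06; 0.44 at day 14 for members at 25% or more of the highest class), and mitochondrially encoded genes were higher for 1 of 13 at day 14 and 5 of 13 at day 28 (median log2 0.46). Markers of proximal tubule were higher for 9 of 9 and 8 of 8 genes at days 14 and 28 (median 7.80-fold and 14.8-fold), and macrophage markers were lower for 5 of 6 at each day (6.38-fold and 11.6-fold) and higher for 1 at day 28. Natural killer cell markers were higher for 5 of 11 and lower for 1 at day 28. Cluster 30, led by Hist1h2ap, held 24, 11 and 1 cells of the class at days 5, 14 and 28.

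Endothelial-like cells at both later days had higher Cxcl12 (2.56-fold and 2.66-fold) and Klf4 (2.39-fold and 2.67-fold), the latter a transcription factor gene that also belongs to the immediate early response. The endothelial list had 5 of 16 members higher and 1 lower at day 14 (median log2 0.23; Esm1 1.52-fold lower) and 2 of 14 higher and 2 lower at day 28 (-0.02; the apelin receptor gene Aplnr 3.33-fold lower). Immediate early genes had medians of log2 1.04 and 1.14 in this class, and mitochondrially encoded genes of -0.32 and 0.27. Interferon genes had medians of 0.64 and 0.70, which were 0.28 and 0.46 without doublet removal, and at day 14 they fell below 1.5-fold also over members with at least 200 UMIs (0.50), with at least 500 genes per cell (0.56) and with a mitochondrial limit of 25% (0.58). Macrophage markers were lower for 4 and 5 of 6 genes (log2 -3.04 and -3.14) and class II genes for 7 of 7 at each day, and proximal tubule markers were higher for 5 of 6 and 7 of 7 (2.16-fold and 5.87-fold). Fibroblast or mural markers were higher for 4 of 4 genes at day 28 (4.91-fold). Fibroblast or mural-like cells could be compared between days 5 and 14, with 54 and 57 cells. Of 30 matrix genes, 5 were higher, among them Lum (4.33-fold) and Mmp2 (1.88-fold), and 4 lower, among them the metalloproteinase inhibitor gene Timp1 (4.22-fold) and Tgfb1 (2.08-fold), with a median log2 of -0.05. The makeup of this class differed, with 46 and 37 cells in cluster 27 and 8 and 20 in cluster 29, which was led by Ren1. Immediate early genes were higher for 20 of 22 members (median log2 1.33) and proximal tubule markers for 3 of 3 (22.7-fold), macrophage markers were lower for 3 of 6 and higher for 1 (log2 -1.86), and the mitochondrially encoded list had a median of -0.46.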

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

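With 1 library per group, results were compared by their counting intervals and by the rule of 1.5-fold. No paired analysis was possible because no library had a partner. Of 178 values of class shares past 1.5-fold, 174 stayed past it in the same direction under the alternatives. So did 477 of 519 values of list medians and 803 of 810 values of named genes. The named genes were picked for the most extreme ratios in these same cells, so their staying past 1.5-fold was largely built in. Within a single cluster per class, 9 of 20 list medians and 31 of 36 named genes stayed past 1.5-fold. Values were counted per alternative, over 24 share ratios, 109 list medians and 54 named genes. The minimums of 20 or 200 UMIs and the rule of 25% of the highest class could not change a named gene (54 of 54 the same in each). Cluster 15 or 17 counted in a class could not change the shares of the other classes. Of 237, 1614 and 810 values, 214, 1196 and 690 stayed within the counting interval. The cause of each change below was not tested, except where a larger minimum of UMIs or a stricter rule left fewer genes. Cluster 17 counted as macrophage-like, cluster 15 counted as proximal tubule-like, the removal of cells of low UMI number or with haemoglobin, and the single cluster per class were chosen after seeing the data.

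Macrophage-like share ratios for Lac.z, day 14 and day 28 were 0.471, 0.175 and 0.071. They were 0.540 and 0.084 (Lac.z, day 28) with mitochondrial share at most 25%, 0.569, 0.211 and 0.084 with libraries clustered separately, and 0.418 and 0.157 (Lac.z, day 14) with cluster 17. All stayed past 1.5-fold. The interferon list in macrophage-like cells (log2 2.13) was 1.887 with separate clustering, 2.049 as the mean of each cell's own CPM, 2.086 with scaling by the median ratio, 2.063 for members at 25% or more of the highest class and 0.688 within cluster 2. The class II list (1.19 and 1.45 at days 14 and 28) was 0.983 and 1.282 as the mean of each cell's own CPM, 0.939 and 1.186 with at least 200 UMIs, and 0.567 and 0.898 within cluster 2. It was 1.261 at day 14 with median-ratio scaling, and at day 28 1.217 without doublet removal, 1.356 with separate clustering and 1.186 at 25% of the highest class. The cluster 2 value at day 14 fell below 1.5-fold.

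The injury list in proximal tubule-like cells with Lac.z (0.30) was 0.152 at the 25% mitochondrial limit and -0.029 with none, 0.241 and -0.240 at resolutions 0.5 and 2, and 1.675 with separate clustering. It was 0.236 with median-ratio scaling, 0.268 without mitochondrial genes in the total, 0.435 with at least 200 UMIs, 0.723 at 25% of the highest class and 0.575 within cluster 1. With cluster 15 counted in the class it was -0.887, past 1.5-fold lower. At day 28 (-1.96) it was -1.477 at the 25% limit, -2.602 at resolution 2, -0.590 with at least 200 UMIs -1.190 within cluster 1 and -2.698 with cluster 15.

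Among results past 1.5-fold as reported, the direction turned for 8 values. Smaller results were not counted here, and some of them changed sign too. Examples are the injury list with Lac.z, given above, and the macrophage-like matrix list at day 28. The latter went from -0.277 to 0.524 for members at 25% or more of the highest class. The macrophage-like haemoglobin list was 0.525 at day 14 without doublet removal, and 2.223, 0.917 and 1.175 (Lac.z, days 14 and 28) without cells of low UMI number or with haemoglobin. T cell-like proliferation at day 14 was 0.017 at resolution 2. With separate clustering, the distal convoluted tubule-like ratio for Lac.z was 0.718 and Mzb1 in T cell-like cells -1.756. Syngr1 at day 14 was 0.140 within cluster 2. Classes under 50 cells, such as neutrophil-like cells at day 28, were too small for expression.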

Other observations

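The tests of free RNA shared by all droplets, of dissociation stress and of the 2 yields were chosen after the results were seen, as were the clock genes as a pattern. For monocytes, the 2 yields and free RNA from another class, the conditions that decided or left them open were also set after the values were seen. A further condition on the hour of collection, that fewer clock genes pass 1.5-fold with Lac.z than at each later day, was tried after the values were seen; it was not met (7 against 8 and 7) and was dropped because it counts genes whatever their size.

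Neutrophil-like cells of the day 5 Lac.z library held more interferon-stimulated RNA than those without Lac.z. All 16 measured members were higher by 1.5-fold (median ratio 6.26), while the median of all measured genes in this class was log2 -0.21. Ifit1 had 5 and 213 UMIs, Irf7 17 and 150 and Isg15 62 and 422. Other cell markers differed in this class too: neutrophil markers were higher for 6 of 11 genes and lower for 1 (median log2 0.94), monocyte markers higher for 3 of 6 and lower for 1 (0.62), and macrophage markers and class II genes each lower for 5 of 6 (-1.67 and -2.90). Haemoglobin UMIs of this class in the Lac.z library lay almost wholly in 1 cell (10008 of 10051). In proximal tubule-like cells the smooth muscle gene Acta2 had 1 UMI at day 5 and 123 with Lac.z, among 11612555 and 34899196 UMIs of the class.

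The interferon list was higher with Lac.z in macrophage-like cells. Free RNA from another class met its planned bound on CPM (1.377 times as high in endothelial-like cells). It was weighed by UMIs per cell only after the values were seen, because free RNA adds UMIs per droplet. By that measure macrophage-like cells held more, with 131 list UMIs per cell against 68.7 in endothelial-like cells. Free RNA shared by all droplets was argued against by proximal tubule-like cells of that library, which held 5.70 per cell, 22.995 times fewer. Monocytes within the class stay open: their markers met the planned bound against them (median log2 -0.201), but that bound was wrong because members went both ways, with Ly6c2 and Plac8 among 3 higher and Fn1, F13a1 and Vcan lower. A whole-kidney interferon state of that library may account for the pattern, since the lowest median over T cell-like, endothelial-like and proximal tubule-like cells was 1.18. The proximal tubule-like part is uncertain, because free RNA was not tested there and distal convoluted tubule-like cells held 3.91 list UMIs per cell. Whether such a state came from Lac.z, that animal or its handling was not separable with 1 library.

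Clock genes differed between days in proximal tubule-like cells, where of 16 measured 6 were higher and 2 lower at day 14, and 5 higher and 2 lower at day 28, when Cry2 (ratio 1.51, and 0.658 in macrophage-like cells) fell just short with 1 UMI added. With Lac.z at day 5, 6 were higher and 1 lower, but ratios were 1.15 for Nr1d1, 1.06 for Arntl, 0.943 for Dbp and 1.95 for Nfil3, against 7.29, 2.22, 0.663 and 6.06 at day 14 and 5.34, 5.08, 0.261 and 4.48 at day 28, while Per1 was 2.44-fold higher both with Lac.z and at day 28 and Npas2 went opposite ways (0.448 and 2.18). A candidate explanation is another hour of collection, which met its planned bound. Of 28 combinations of gene, other class and day, 24 (85.714%) went the same way. Over all measured genes 70.3% and 62.9% did so at days 14 and 28. With Lac.z, 3 of 9 combinations of clock genes and 68.7% over all genes did so. This count reads only whether classes went the same way, not whether the genes differed as another hour would have it. Nr1d2, unlike Nr1d1, had ratios of 1.10 and 0.825 in proximal tubule-like cells at days 14 and 28. The 4 exceptions were Nr1d1 in endothelial-like cells at both days, Dbp in T cell-like cells at day 14 and Nfil3 in macrophage-like cells at day 28; the combinations share the day 5 library, no hour is given in the labels, and a change of the clock with time after injury stays open and untested. A shift of cell states stays open as well, since cluster 6, with Nr1d1 among its leading genes, held 15, 754 and 1206 cells at days 5, 14 and 28 and Nr1d1 within cluster 1 alone had log2 0.868 and 0.402, the latter below 1.5-fold (Dbp -3.26 at day 28), and so does dissociation stress, since 2 clock genes (Dbp and Cry1) were lower and the bound set against it was 3.

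The macrophage-like share was lower in the day 5 Lac.z library. A lower yield of proximal tubule cells alone without Lac.z would give every other class 1 ratio. Within counting error only, such a yield was argued against as the whole cause. The intercalated-like ratio was 2.008 (1.129 to 3.687), from 19 cells without and 38 with Lac.z. Its interval lay above the macrophage-like one (0.443 to 0.501) as reported and in all 10 alternatives of the shares. Among these, counting cluster 15 as proximal tubule-like could not change either share. With a mitochondrial limit of 25% the intercalated-like ratio was 1.373. The distal convoluted tubule-like interval also lay above the macrophage-like one except with separate clustering (0.718), where the day 5 library had no loop of Henle-like cluster. The intervals leave out spread between preparations, so unequal ratios from such spread were not excluded. A lower yield of all tubule cells stays open. The T cell-like (0.544 to 0.737) and neutrophil-like intervals (0.577 to 0.919) lay above the macrophage-like one except with separate clustering (T cell-like 0.628, macrophage-like 0.569). The monocyte-like interval (0.792 to 1.979) lay above it as reported and was not followed through the alternatives. The endothelial-like (0.483 to 0.781), dendritic cell-like (0.406 to 0.919), plasmacytoid dendritic cell-like (0.015 to 0.576) and fibroblast or mural-like intervals (0.211 to 0.631) overlapped it. Among named immune cells the macrophage-like ratio was 0.925 (0.870 to 0.983), an interval that did not hold 1. With 1 library per group a lower yield of all tubule cells cannot be told apart from an effect of Lac.z on macrophages.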
